A study of Mus musculus with 14 samples.

How the data were processed

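RNA of male germ cells from the testes of C57BL/6 mice at postnatal days 3 and 7 was measured by sequencing in 14 libraries. Per the labels, RNA was taken with the AllPrep DNA/RNA Micro kit and libraries were made with the TruSeq Stranded mRNA LT kit. The labels state no sort of the cells and do not say whether the 2 replicates of a group come from separate animals. The targeted genes were deleted with the germline driver Vasa-Cre.

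The deposited values are RPKM, read numbers scaled to transcript length and to the mapped reads of the library, made by the authors for 24340 gene symbols per library. The labels name TopHat2 2.1.1 and Cufflinks 2.1.1 on the mm10 genome and state neither the role of each nor the annotation used. The files analysed here hold no counts or library totals. Depth was therefore estimated from the smallest steps between RPKM values of 3503 genes with a single annotated transcript of 800 to 8000 nucleotides. Of the genes used in each library, 71.1 to 82.2% lay within 0.2 of a whole number of fragments, where chance gives 40%. The estimate ran from 13.2 to 46.9 M (mega) fragments per library. Gene coordinates were taken from GENCODE M21 on GRCm38, which held 98.3% of the symbols.

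Values were used as log2(RPKM + 1) with no further scaling. Genes with at least 1 RPKM in at least 2 of the 14 libraries were tested, which kept 14772 genes and removed 9568. Entries for small RNAs were kept, although the library kit is for mRNA, so their values are not read as levels of mature small RNAs. Models were fitted with limma 3.58.1 (trended eBayes) in R 4.3.3, with 1 coefficient per group over all 14 libraries, so that the groups share an estimate of the spread with 7 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within each of 10 comparisons, with a threshold of 0.05. The comparisons were P3 Ctrl against P3 WT, each P3 knockout against P3 Ctrl, P3 DKO against each single knockout, P7 DKO against P7 Ctrl, P7 Ctrl against P3 Ctrl, the difference between the DKO changes at P7 and P3, and the departure of P3 DKO from the sum of the single losses. The median SE of a log2 change was 0.185 (0.262 for the interactions). With the 7 residual degrees of freedom alone this puts a 95% interval at plus or minus about 0.438 (0.62). The eBayes tests add prior degrees of freedom, so the intervals that belong to them are narrower. Leaving out 1 library leaves a group of 1, which is then assumed to vary like the other groups.

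A set of 22 gene lists, written before the files were opened, was tested with camera of limma at its preset correlation of 0.01, two-sided, with adjustment over the lists of a comparison. The lists held 483 genes, 479 of them in the files, and a few genes are in more than 1 list. They cover spermatogonial stem cells, differentiating spermatogonia, the piRNA pathway and de novo methylation, pan-germ-cell genes, pluripotency, meiotic prophase, spermatids, S phase, G2 and mitosis, p53 targets, H3K9 methylation enzymes and readers, the Rhox cluster, Mage and Xlr families with other germline genes repressed by H3K9 methylation, imprinted genes, hypoxia targets, immediate early genes, and markers of Sertoli, Leydig, stromal, leukocyte, endothelial and erythroid cells. Of 67 list calls, 1 also passed when camera estimated the correlation, that of the Rhox list in P3 DKO. The test fry of limma (with statmod 1.5.0) was run as an alternative and asks whether the genes of a list move on balance 1 way or, in its mixed form, in either direction, without comparing the list with other genes.

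The genes named were fixed by a rule. It took Kdm3a and Kdm3b, then the 8 largest rises and 8 largest falls among genes past the threshold whose libraries do not overlap between groups in P3 DKO, P7 DKO and the age comparison, and 4 and 4 elsewhere. It added up to 4 members past the threshold from each list that passed or held at least 3 such members, and the passing members of the H3K9 list. From lists with none passing it took the 2 members with the highest mean RPKM, as values. Predicted genes and small RNAs were counted but not named, except in comparisons with 5 calls, where they were added after their values were seen. A gene that the rule also took is not reported here, though it stays in every fit and count of changed genes.

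Changes were compared between comparisons by the overlap of calls and by the correlation of log2 changes across genes, beside 100 simulated sets of unchanged groups that share the same control libraries. The spread of the simulated values was estimated without the single knockout groups. For comparison with the DKO changes the age change was also taken from P3 WT to P7 Ctrl, which spans a difference in genotype and Cre. The model was tested on simulated data: of 100 genes given a log2 change of 1 in P3 DKO, 69% were recovered, with 10 false calls, and 92% at a log2 change of 2. Groups of 2 allow no permutation of the samples that could reach a p under 0.05, so none was run.

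Alternatives set before the data were examined were median-centring, quantile normalization, a pseudocount of 0.1, no filter on low values, replicate number as a covariate, limma array weights, an added limit of 2-fold, only the libraries of the groups compared, leaving out each library in turn, and for lists camera with an estimated correlation and fry. The settings without small RNA entries, without the pair of libraries with high Sertoli transcripts, and without each library for the list tests were chosen after seeing the data. Figures and tables were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Raw reads were not reprocessed, and transcript isoforms and transposable elements were left out because the files give values per gene symbol.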

Results

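Transcripts of male germ cells from postnatal C57BL/6 mouse testis were measured in 14 libraries that form 7 groups of 2. At postnatal day 3 (P3) the groups were wild type (P3 WT), carriers of the germline driver Vasa-Cre with 1 remaining copy of Jmjd1a and of Jmjd1b (P3 Ctrl), animals without Jmjd1a but with 1 copy of Jmjd1b (P3 Jmjd1aKO), the converse genotype (P3 Jmjd1bKO) and animals without either gene (P3 DKO). At day 7 (P7) there were controls of the same genotype as P3 Ctrl and DKO animals. Jmjd1a and Jmjd1b, listed under the symbols Kdm3a and Kdm3b, encode enzymes that remove methyl groups from lysine 9 of histone H3. Levels are RPKM, given as mean ± SD of 2 libraries, and changes are log2 changes of RPKM + 1 ± SE from limma. The labels do not say whether the replicates of a group come from separate animals, so the p-values measure only the spread between these samples. The depth estimated from the RPKM values ran from 13.2 to 14.6 M (mega) fragments in P3 WT and from 21.3 to 24.5 M in P7 Ctrl. It was 21.6 to 21.8 M in P7 DKO, 38.5 to 42.7 M in P3 Ctrl and 44.1 to 46.9 M in P3 DKO. It was 26.3 and 39.5 M in P3 Jmjd1aKO, and 25.5 and 41.2 M in P3 Jmjd1bKO. Replicates correlated across genes at r = 0.938 in P3 Jmjd1bKO, the lowest of the groups, and at r = 0.981 in P7 Ctrl, the highest.

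Germ cell transcripts were abundant in every library: Ddx4, the germ cell RNA helicase also called Vasa, lay between 169.5 and 307 RPKM. Transcripts of Sertoli cells, the supporting cells of the tubule, set a pair of libraries apart. Amh, the hormone made by immature Sertoli cells, stood at 108 RPKM in P3 Jmjd1aKO replicate 2 and 149.6 RPKM in P3 Jmjd1bKO replicate 2, against 3.33 and 2.3 RPKM in the other replicate of each genotype. In P3 WT it stood at 16.6 and 22.6 RPKM, and in the remaining libraries between 3.09 and 9.77 RPKM. The inhibin subunit gene Inha followed the same order, with 165 and 206 RPKM in that pair against 6.33 and 6.19 RPKM in P3 Ctrl. These values stand beside every comparison of the single knockouts.

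**Figure D1:**
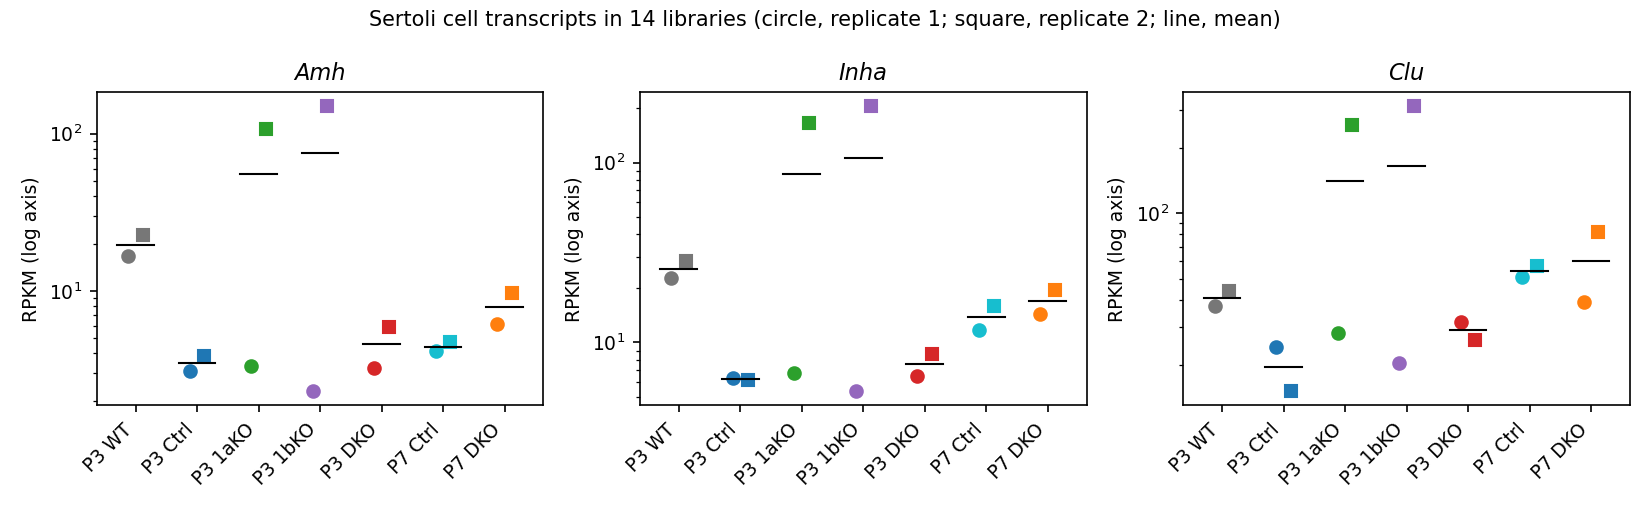
RPKM of the Sertoli cell genes Amh, Inha and Clu on a log axis in the 7 groups, with a circle for replicate 1, a square for replicate 2 and a line for the mean. Replicate 2 of P3 Jmjd1aKO and of P3 Jmjd1bKO lies above all other libraries for each gene, with Clu at 255 and 312 RPKM.

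Against controls of the same age, the transcripts of the deleted genes were lower in the groups that lack them by genotype, with 1 exception in the test. RNA of the deleted genes remained in every such group, with more Kdm3a in P3 DKO than in P3 Jmjd1aKO. The levels thus do not show how complete the deletion was. Kdm3a (chromosome 6, 71588972 to 71632990, GRCm38) fell from 27.3 ± 1.5 RPKM in P3 Ctrl to 9.83 ± 0.011 in P3 Jmjd1aKO (log2 change -1.39 ± 0.11, adjusted p = 0.000891) and to 13.2 ± 1.55 in P3 DKO (adjusted p = 0.00672). It stood at 25.7 ± 0.48 RPKM in P3 Jmjd1bKO, and Kdm3b at 11.9 ± 2.9 in P3 Jmjd1aKO. Kdm3b (chromosome 18, 34777047 to 34838660) fell from 11.8 ± 2.39 to 4.37 ± 0.156 RPKM in P3 DKO (log2 change -1.25 ± 0.21, adjusted p = 0.0219). Its level in P3 Jmjd1bKO was 6.12 ± 1.97 RPKM, a log2 change of -0.87 ± 0.21 that did not pass (adjusted p = 0.965). At P7 Kdm3a fell from 27.1 ± 0.0714 to 8.28 ± 0.978 RPKM and Kdm3b from 16.7 ± 0.83 to 6.61 ± 0.167 RPKM (adjusted p = 1.64e-05 and 0.00203). P3 WT held 44.6 ± 0.831 RPKM of Kdm3a and 26.9 ± 0.0082 RPKM of Kdm3b, above the heterozygous P3 Ctrl (log2 change from WT to Ctrl -0.69 ± 0.11 and -1.13 ± 0.21, adjusted p = 0.0352 and 0.0496).

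**Figure D2:**
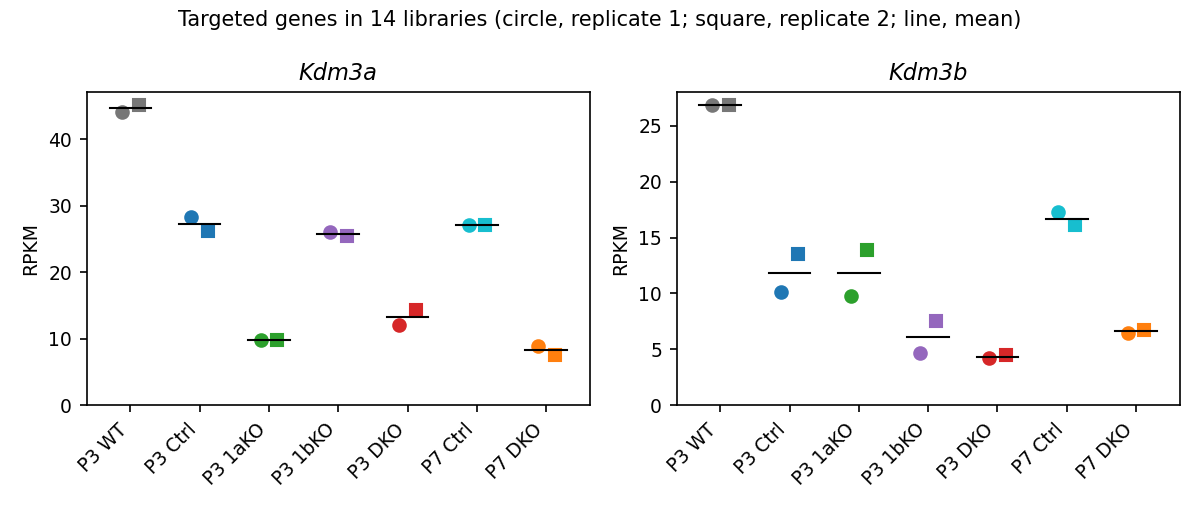
RPKM of Kdm3a and Kdm3b on linear axes in the 7 groups, with a circle for replicate 1, a square for replicate 2 and a line for the mean. Kdm3a is lowest in P7 DKO (8.28) and P3 Jmjd1aKO (9.83), and Kdm3b in P3 DKO (4.37).

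The comparison of P3 Jmjd1aKO with P3 Ctrl asks what loss of Jmjd1a changes while 1 copy of Jmjd1b remains, and it gave few single genes. Eml2, a microtubule-associated protein gene, rose from 4.6 ± 1.45 to 14.8 ± 2.1 RPKM (log2 change 1.52 ± 0.19, adjusted p = 0.0411), and Kdm3a itself fell. The other 3 of the 5 genes past the threshold, chosen after their values were seen, were 1700015G11Rik, which fell from 5.26 ± 0.849 to 0.326 ± 0.207 RPKM, Mir6898, listed at 0 in both P3 Ctrl libraries and at 43.3 ± 4.1 RPKM in the knockout, and Mir93, listed at 0 in the knockout and at 22.2 ± 1.5 RPKM in P3 Ctrl. Calls of Eml2 and 1700015G11Rik were lost with a pseudocount of 0.1, without a filter on low values and with replicate number as a covariate. At an unadjusted p under 0.05 there were 1484 genes. Cd209c, a C-type lectin gene and likewise singled out after its values were seen, stood at 78.1 and 48 RPKM against 12.7 and 6.78 in P3 Ctrl and did not pass. S phase and DNA replication genes were lower as a list: none of the 28 passed alone, 9 were lower adjusted over the list alone, and the median change was -0.28 (adjusted p = 1.55e-11, and adjusted p = 0.337 with an estimated correlation). The replication clamp gene Pcna stood at 214 ± 21.1 against 269 ± 26.8 RPKM (log2 -0.33 ± 0.10, adjusted p = 0.359). Rhox homeobox genes, an X-linked cluster expressed in the reproductive tract, were higher as a list, with a median of 0.46 over 13 genes and 5 higher and 1 lower adjusted over the list alone (adjusted p = 2.53e-05, and adjusted p = 0.0511 with an estimated correlation). Rhox1 stood at 34.9 ± 0.378 against 24.1 ± 0.802 RPKM (log2 0.52 ± 0.12, adjusted p = 0.259).

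In the same comparison the list of G2 and mitosis genes was lower at a median of -0.32 (adjusted p = 7.04e-06, and adjusted p = 0.422 with an estimated correlation), but it did not pass without P3 Ctrl replicate 2 (adjusted p = 0.288) or P3 Jmjd1aKO replicate 1 (0.654). Lists of somatic cells were higher beside the Sertoli transcripts of replicate 2: Sertoli (adjusted p = 9.07e-05, and adjusted p = 0.399 with an estimated correlation), Leydig (0.0094 and 0.384 in the same order) and stromal markers (0.000283 and 0.337). None of their members passed alone. Without P3 Jmjd1aKO replicate 2 these 3 lists did not pass (adjusted p = 0.906, 0.985 and 0.237), and the Leydig list also failed without P3 Ctrl replicate 2 (0.144). Pan-germ-cell genes were lower, and pluripotency, immediate early, leukocyte and erythroid genes were higher, as lists with all libraries (adjusted p = 0.00121, 0.0229, 0.0361, 0.0491 and 0.0361). Under quantile normalization none of these 5 lists passed (0.288, 0.0531, 0.0531, 0.0991 and 0.0531), nor did the leukocyte list with replicate number as a covariate (0.0632). With an estimated correlation these gave adjusted p = 0.337 for each of the 5, and without P3 Jmjd1aKO replicate 2 0.0644, 0.0558, 0.377, 0.648 and 0.985. The pluripotency call also ended without P3 Ctrl replicate 1 (0.0728) or P3 Jmjd1aKO replicate 1 (0.102), the immediate early and leukocyte calls without P3 Ctrl replicate 2 (0.354 and 0.325) and the erythroid call without either P3 Ctrl library (0.117 and 0.0515). Without both libraries with high Sertoli transcripts, a setting chosen after seeing the data, P3 Jmjd1aKO is a single library. The list medians were then -0.374 for S phase, -0.60 for G2 and mitosis and 0.494 for Rhox genes.

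P3 Jmjd1bKO against P3 Ctrl asks what loss of Jmjd1b changes with 1 copy of Jmjd1a left. It gave 3 entries in limma, all microRNA loci with values at 0 in either group. The libraries were made with an mRNA kit, and Mir93 (chromosome 5, 138165523 to 138165610) lies within Mcm7 (138164583 to 138172422). An effect of the genotype on mature microRNAs is thus not shown. Mir8105 was listed at 0 in both P3 Ctrl libraries and at 21.5 ± 1.91 RPKM in the knockout. Mir93 and Mir23a were listed at 0 in the knockout and at 22.2 ± 1.5 and 81.2 ± 43.1 RPKM in P3 Ctrl. With small RNA loci left out, a setting chosen after seeing the data, limma called 0 genes, beside 268 at an unadjusted p under 0.05 with them. Without P3 Ctrl replicate 2 the count was 7 and without P3 Jmjd1bKO replicate 1 it was 5. Dazl, an RNA-binding protein of germ cells, stood at 369 ± 58.3 against 399 ± 13.5 RPKM and Rhox13, an X-linked homeobox gene, at 26.3 ± 2.63 against 25.9 ± 0.298 RPKM, neither past the test. The Rhox list had a median of -0.06 and a mean of 0.06, with the test pointing down (adjusted p = 0.46). The 7 lists that passed with all libraries were Sertoli, Leydig, stromal, immediate early, and G2 and mitosis genes, higher (adjusted p = 4.42e-07, 0.000439, 0.000316, 0.0275 and 0.000471), and piRNA pathway and endothelial genes, lower (0.0103 and 0.029), with no member past the gene test. With an estimated correlation their adjusted p ran from 0.571 to 0.628. None of them passed without P3 Jmjd1bKO replicate 2, the library with high Sertoli transcripts (adjusted p from 0.769 to 0.916). Without P3 Ctrl replicate 1 the G2 and mitosis list pointed down (0.345), and the piRNA and endothelial calls ended (0.0798 and 0.239). Without P3 Ctrl replicate 2 the piRNA, immediate early, Leydig, stromal and endothelial calls ended (0.0709, 0.509, 0.0709, 0.167 and 0.0536).

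Germ cells without either demethylase at P3 were compared with P3 Ctrl to ask what their joint loss changes at day 3. Among genes of DNA replication 14 of the 28 in the S phase list were lower, and the call of the list is lost with an estimated correlation (adjusted p = 0.259). Rrm2 and Rrm1, the subunits of ribonucleotide reductase, fell from 47.3 ± 18.9 to 21 ± 1.39 RPKM and from 95.4 ± 20.6 to 53.4 ± 0.0402 RPKM, and Mcm5, a subunit of the replicative helicase (chromosome 8, 75109569 to 75128439), from 133 ± 19.7 to 68.2 ± 0.928 RPKM (log2 change -0.94 ± 0.12, adjusted p = 0.0121). Several Rhox genes rose, among them Rhox10 (chromosome X, 38066475 to 38071691), which acts in the formation of spermatogonial stem cells, from 26.3 ± 3.72 to 50.7 ± 4.83 RPKM (log2 change 0.92 ± 0.19, adjusted p = 0.0317). The largest rise of all genes past the threshold was that of Cd209c (chromosome 8, 3940222 to 3954746), which stood at 374 and 137 RPKM against 12.7 and 6.78 (log2 change 4.46 ± 0.42, adjusted p = 0.00278).

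In the S phase and replication list none was higher in P3 DKO and 14 did not pass, with 24 lower adjusted over the list alone. The median change was -0.59 (adjusted p = 5.90e-18, and adjusted p = 0.259 with an estimated correlation). The origin licensing factor Cdc6 fell from 14.1 ± 0.714 to 7.58 ± 0.757 RPKM. In the G2 and mitosis list 4 of 27 were lower and 23 did not pass, with 15 lower adjusted over the list alone (median -0.62, adjusted p = 2.68e-10, and adjusted p = 0.732 with an estimated correlation). The cyclins Ccna2 and Ccnb1 fell from 86.7 ± 19.2 to 48.7 ± 5.03 RPKM and from 108 ± 17 to 67 ± 14.3 RPKM. In the Rhox cluster 5 of 13 genes were higher and none lower, with 11 higher and 1 lower adjusted over the list alone (median 0.69, adjusted p = 6.17e-06, and adjusted p = 0.0368 with an estimated correlation). Rhox9 rose from 3.24 ± 0.531 to 10.4 ± 1.13 RPKM. These 3 list calls held without each of the 4 libraries in turn, a setting added after seeing the data.

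Genes of the spermatogonial stem cell list went both ways at P3, with 3 higher, 2 lower and 27 not passing (3 higher and 5 lower adjusted over the list alone, list adjusted p = 0.254). Pax7, a marker of rare stem cells, rose from 2.48 ± 0.131 to 7.85 ± 1.97 RPKM and the progenitor factor Sox3 from 8.82 ± 0.28 to 15.7 ± 0.923 RPKM. Plvap, expressed in stem-like spermatogonia and in fenestrated endothelium, fell from 15.8 ± 1.16 to 8.29 ± 1.54 RPKM. The differentiating list had 1 higher and 3 lower of 15 (2 higher and 5 lower adjusted over the list alone, adjusted p = 0.198): Dmrtb1, a regulator of the switch from mitosis to meiosis, rose from 4.31 ± 0.0504 to 8.35 ± 0.15 RPKM, while the differentiation factor Sohlh2 and the methyltransferase Dnmt3b fell, as did Ccna2. The pluripotency list had 3 higher of 19 (Dppa3, Klf4 and Dppa5a) and none lower (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.254). Among H3K9 methylation genes Ehmt2, which encodes the methyltransferase G9a, rose from 109.7 ± 0.455 to 168 ± 7.81 RPKM and the hemimethylated-DNA reader Uhrf1 fell from 204 ± 30.9 to 116 ± 9.7 RPKM. The imprinted genes Peg10 and Mirg rose and H19 and Peg13 fell. The Mage list had a median of 0.13 while its test pointed down (adjusted p = 0.924), and the endothelial list a median of -0.18, a mean of 0.04 and a test pointing up (0.909). Stromal markers had a median of 0.54 with none of 15 past the gene test (adjusted p = 0.117), and passed as higher without the pair of libraries with high Sertoli transcripts (6 higher and 0 lower, adjusted p = 0.00102).

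In all, 661 of 14772 genes passed in P3 DKO, 322 higher and 339 lower. Median-centring gave 277 higher and 503 lower. Without a filter on low values 1071 were higher and 513 lower, 125 and 240 with a pseudocount of 0.1, and 127 and 34 with an added limit of 2-fold on the filtered genes. With only the libraries of the 2 groups the count was 17. Other large rises were those of Dbhos, a transcript annotated opposite Dbh, to 13.7 ± 7.8 RPKM, and of Nol4 to 10.7 ± 1.24. Klk1b24, Otx2, Ndrg2, Ripk3 and Gabbr1 also rose, with log2 changes from 1.56 to 1.83. Large falls were those of the endothelial transcription factor gene Sox18, from 20.6 ± 1.27 to 5.43 ± 1.66 RPKM, and of Ifi27l2a, Exoc3l, Nxph4, Gpsm3, Gngt2 and Krt17 (log2 changes from -1.94 to -1.56). The count rested on both replicates of each group. It was 150 without P3 Ctrl replicate 1, 10 without P3 Ctrl replicate 2, 117 without P3 DKO replicate 1 and 21 without P3 DKO replicate 2. Of the 44 named calls leaving out these libraries ended 30, 41, 32 and 38 and reversed none. The calls of Rrm2, Ccnb1, Gpsm3 and H19 were lost without a filter on low values, with a pseudocount of 0.1 and under quantile normalization. Those of Ccna2 and Dppa3 were lost with the pseudocount and quantile normalization, those of Klf4, Rhox9, Nxph4 and Peg13 with the pseudocount, and those of Sohlh2 and Uhrf1 under quantile normalization. The count rose to 1931 without the libraries with high Sertoli transcripts, which belong to neither group but enter the shared estimate of the spread.

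**Figure D3:**
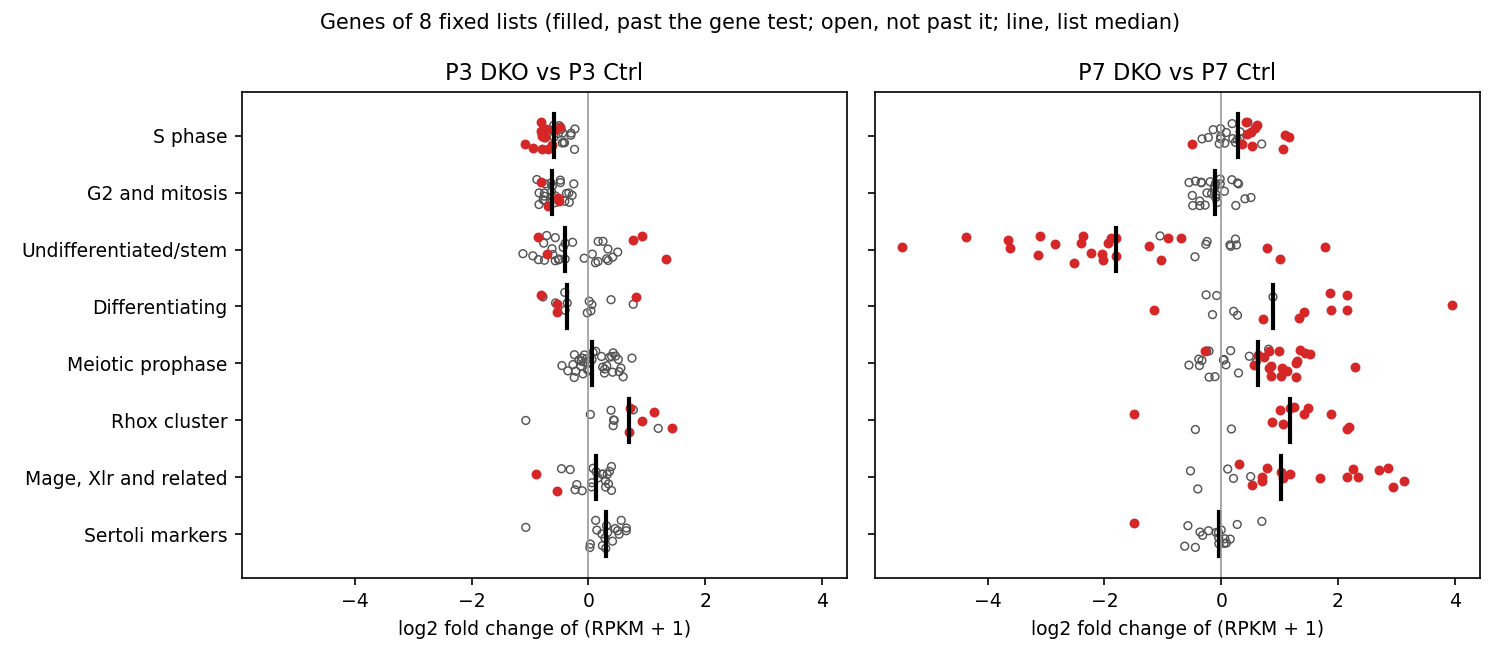
Log2 change of RPKM + 1 (horizontal axis) for each tested gene of 8 lists (vertical axis) in P3 DKO and P7 DKO against controls of the same age, with filled points past the gene test, open points not past it and a line at the list median. The S phase median is -0.59 at P3 and 0.30 at P7, and the stem cell median -0.40 and -1.80.

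At P7 the comparison of DKO with control germ cells, which asks what joint loss changes at day 7, opposed stem cell and differentiation genes. Plvap (chromosome 8, 71497765 to 71511752) fell from 79.4 ± 0.225 to 0.822 ± 0.104 RPKM (log2 change -5.46 ± 0.19, adjusted p = 1.14e-06). Foxc2, a transcription factor of quiescent stem spermatogonia (chromosome 8, 121116171 to 121118895), fell from 75.8 ± 2.18 to 2.8 ± 1.19 RPKM (log2 change -4.37 ± 0.29, adjusted p = 1.64e-05). Dmrtb1 (chromosome 4, 107676290 to 107684230) rose from 8.68 ± 1.16 to 149 ± 7.69 RPKM (log2 change 3.96 ± 0.17, adjusted p = 2.46e-06). Stra8, the retinoic acid target required for meiotic entry (chromosome 6, 34920163 to 34939344), rose from 58.5 ± 3.57 to 224 ± 73.5 RPKM (log2 change 1.88 ± 0.28, adjusted p = 0.00091).

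The list of undifferentiated spermatogonia and stem cells had 21 of 32 genes lower, 3 higher and 8 not passing, with the same counts adjusted over the list alone and a median of -1.80 (adjusted p = 2.37e-08, and adjusted p = 0.134 with an estimated correlation). The mesodermal factor gene T fell from 18 ± 0.61 to 0.516 ± 0.219 RPKM and Lhx1, a target of GDNF signalling, from 39 ± 0.441 to 2.48 ± 1.77 RPKM. The endothelial list also fell, with 4 of 8 lower and none higher, also adjusted over the list alone (median -0.53, adjusted p = 0.0178, and adjusted p = 0.612 with an estimated correlation). Of its members Kdr, the VEGF receptor, fell from 3.71 ± 0.0721 to 0.316 ± 0.177 RPKM and the junction protein gene Cdh5 from 2.77 ± 0.0655 to 0.217 ± 0.245 RPKM. In the differentiating list 8 of 15 were higher, 1 lower and 6 not passing, with 9 higher and 2 lower adjusted over the list alone (median 0.89, adjusted p = 0.00131, and adjusted p = 0.12 with an estimated correlation). Both patterns were larger in P7 DKO replicate 2. Against the P7 Ctrl mean the stem cell median was -1.21 in replicate 1 and -2.1 in replicate 2, and the differentiating median 0.708 and 1.07. Sohlh2 rose from 51.6 ± 1.11 to 233 ± 9.98 RPKM and Rhox13 from 21 ± 0.294 to 97.2 ± 13.7 RPKM. Of 35 meiotic prophase genes 18 were higher, 1 lower and 16 not passing, with 19 higher and 2 lower adjusted over the list alone (median 0.64, adjusted p = 0.000854, and adjusted p = 0.386 with an estimated correlation). Sycp1, of the synaptonemal complex, rose from 49 ± 1.52 to 126 ± 19 RPKM and Gm1564, now named Meioc, from 3.66 ± 0.283 to 21.9 ± 4.2 RPKM.

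**Figure D4:**
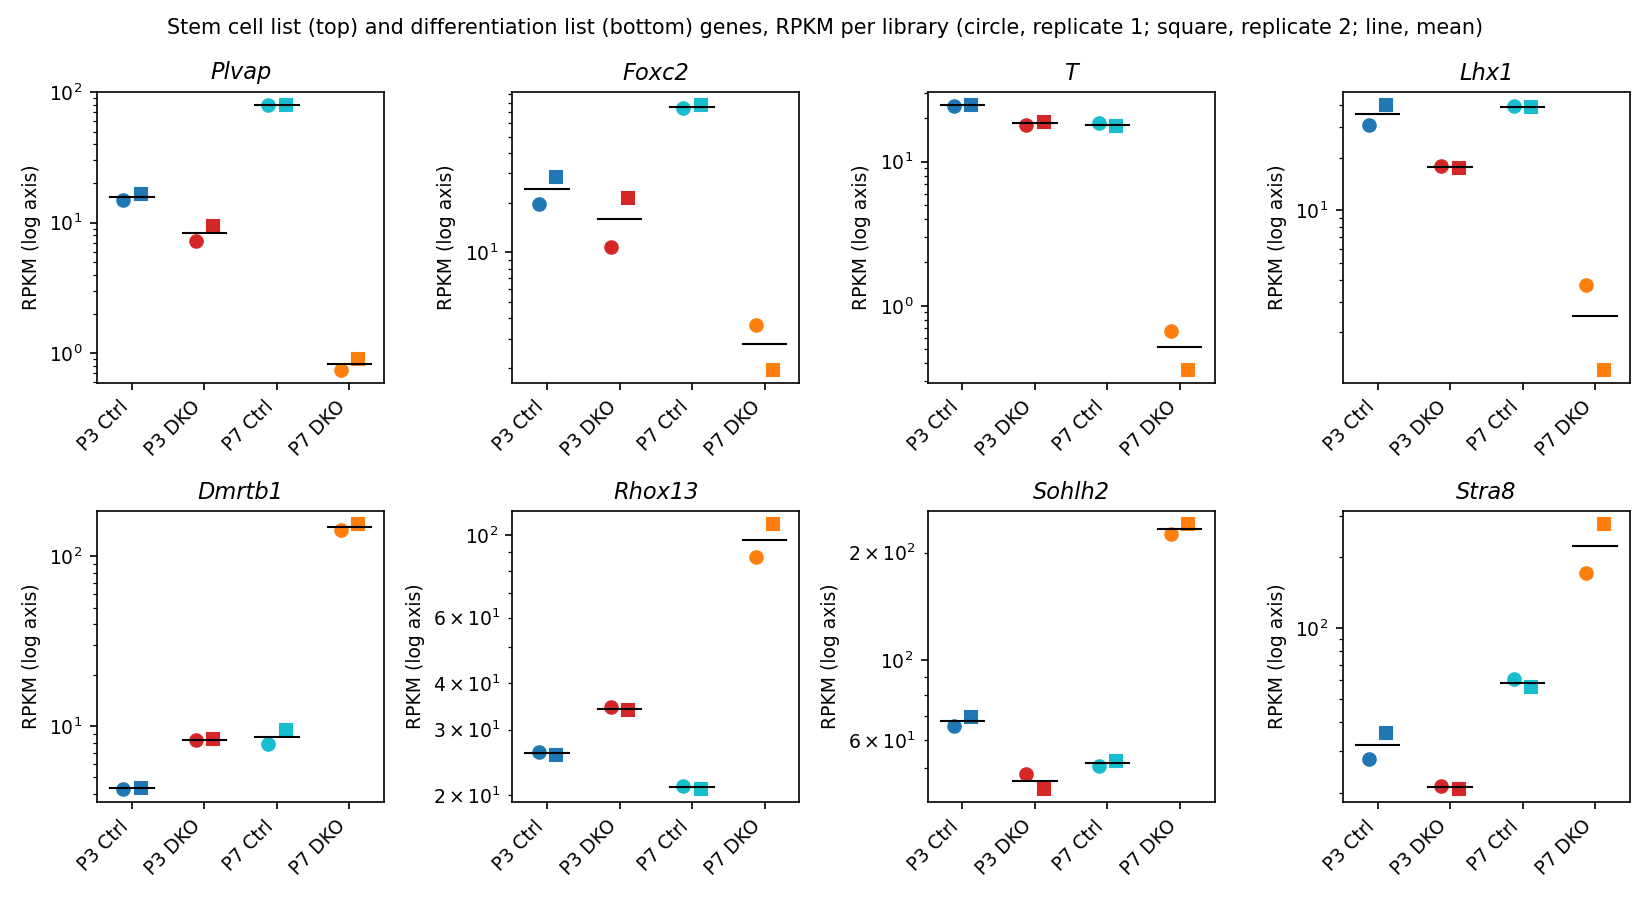
RPKM on log axes of the stem cell list genes Plvap, Foxc2, T and Lhx1 (top) and the differentiation list genes Dmrtb1, Rhox13, Sohlh2 and Stra8 (bottom) in P3 and P7 controls and DKO, with a circle for replicate 1, a square for replicate 2 and a line for the mean. At P7 both DKO libraries lie below both controls in the top plots, as for Lhx1 (2.48 against 39), and above them in the bottom plots.

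The Rhox and Mage families, most of them X-linked, rose as lists in P7 DKO. The Rhox cluster had 10 of 13 genes higher and 1 lower, with the same counts adjusted over the list alone (median 1.17, adjusted p = 2.94e-05, and adjusted p = 0.053 with an estimated correlation). Rhox9 rose from 1.82 ± 0.295 to 11.8 ± 1.37 RPKM and Rhox6 from 1.31 ± 0.387 to 7.52 ± 1.09, while Rhox5 fell from 7.21 ± 0.342 to 1.96 ± 0.781. Of 21 genes of the Mage and Xlr families and other germline genes repressed by H3K9 methylation, 16 were higher and none lower, with 18 higher and 2 lower adjusted over the list alone (median 1.03, adjusted p = 2.37e-08, and adjusted p = 0.12 with an estimated correlation). Magea4, a melanoma antigen gene (chromosome X, 72222017 to 72222964), rose from 0.856 ± 0.0947 to 15.6 ± 5.41 RPKM (log2 change 3.12 ± 0.28, adjusted p = 7.34e-05), and Magea2, Magea3 and Magea6 rose by 2.71 to 2.94 on the log2 scale. Of the S phase list 10 of 28 were higher and 1 lower, with 11 higher and 1 lower adjusted over the list alone (median 0.30, adjusted p = 0.0192, and adjusted p = 0.828 with an estimated correlation). The S phase call was lost under quantile normalization (adjusted p = 0.563) and without P7 DKO replicate 1 (0.101). Its members that rose most were the cyclin E genes, Ccne2 from 4.43 ± 0.144 to 11.1 ± 0.538 RPKM and Ccne1 from 16.3 ± 0.695 to 35.5 ± 7.94 RPKM, with the replication factor Gins2. The other 6 list calls at P7 held without each of the 4 libraries in turn.

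Other lists did not pass at P7 but most held genes that did. The piRNA pathway list had 7 of 22 lower and none higher (1 higher and 7 lower adjusted over the list alone, adjusted p = 0.07). Piwil4, the nuclear PIWI protein of fetal germ cells, fell from 11.8 ± 1.03 to 2.33 ± 1.85 RPKM, and Exd1, Tdrd7 and Tdrd1 also fell. Pan-germ-cell genes had 7 higher and 3 lower of 15, also adjusted over the list alone (adjusted p = 0.171), with rises of Taf7l, Nxf2, Sycp3 and Hormad1. Pluripotency genes had 2 higher and 5 lower of 19, the same over the list alone (0.962, median 0.01 with a test pointing down). Pou5f1 fell from 68.6 ± 1.69 to 14.4 ± 6.31 RPKM, Sox2 and Esrrb fell, and Nanog rose from 0.871 ± 0.139 to 3.31 ± 0.179. Spermatid genes had 4 higher and 3 lower of 14 (4 higher and 4 lower adjusted over the list alone, 0.962), with Spaca1 and Odf2 up and Tnp1 and Ldhc down. None of 27 G2 and mitosis genes passed in limma (0.377, median -0.11), and Cdca8 stood at 113 ± 8.46 against 114 ± 0.585 RPKM. Imprinted genes had 9 higher and 5 lower of 32 (10 higher and 5 lower adjusted over the list alone, 0.784): H19 fell from 97.2 ± 2.45 to 2.82 ± 1.24 RPKM, Igf2 and Rian fell, and Snrpn rose. Of the H3K9 list, Kdm4c, Trim28 and Wiz were higher and Uhrf1 and Cdyl lower, with 1 higher and 0 lower adjusted over the list alone (0.962, median 0.06 and mean 0.03 with a test pointing down). All 5 of these H3K9 calls depend on a setting. That of Kdm4c was lost without a filter on low values, with a pseudocount of 0.1 and under quantile normalization. Those of Trim28 and Wiz were lost under quantile normalization and that of Cdyl with median-centring. The Uhrf1 call was lost with median-centring, without a filter and with replicate number as a covariate. The Sox2 call was lost without a filter and under quantile normalization.

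No stress list passed at P7, nor any somatic list besides the endothelial one. The p53 target list had 7 higher and 4 lower of 23, the same over the list alone (adjusted p = 0.962, median -0.04 with a mean of 0.15 and a test pointing up): the kinase Plk2, Eda2r and Phlda3 rose and the repair factor Xpc fell. Hypoxia targets had 6 higher and 2 lower of 22 (7 higher and 2 lower adjusted over the list alone, 0.157), with Vegfa rising from 1.69 ± 0.123 to 5.14 ± 0.385 RPKM. Immediate early genes had 1 higher and 3 lower of 19 (0.233), with Hspa1b up and Zfp36, Socs3 and Btg2 down (all but Socs3 lost without a filter on low values, and Hspa1b under quantile normalization), and stromal markers 3 lower of 15 (0.304, median 0, mean -0.34), namely Pdgfrb, Col1a1 (lost without a filter) and Pdgfra. Sertoli markers had 1 lower of 18 (0.718), Leydig markers 1 higher of 9 (0.644, median -0.00129, mean 0.10), leukocyte markers 2 lower of 11 (0.484, median 0.01, mean -0.28) and erythroid markers none of 6 (0.925). Counts adjusted over the list alone were the same for these last 6 lists.

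Over all genes 4954 of 14772 passed at P7, 2569 higher and 2385 lower, of which 648 and 858 moved by at least 2-fold. The split into higher and lower was 2890 and 2089 with median-centring and 2087 and 2229 after quantile normalization. Cd209c, at 9.9 ± 0.0179 RPKM in controls, reached 1587 ± 116 (log2 change 7.19 ± 0.42), and Dbhos rose from 0.74 ± 0.135 to 72.9 ± 6.25 RPKM. H2-K1, an MHC class I heavy chain, rose from 3.8 ± 0.0208 to 38.4 ± 9.84 RPKM, and Cthrc1 and Ly6k by 3.84 and 3.36 on the log2 scale. Klk1b24 was listed at 0 in both P7 Ctrl libraries and at 9.34 ± 5.54 RPKM in P7 DKO. Falls of similar size were those of the homeobox genes Prrx2 and Dlx3, of Smkr-ps and of the sphingosine kinase gene Sphk1 (log2 changes from -4.00 to -3.86). Rpl26 stood at 7.03 RPKM and at 0 in the P7 DKO libraries, against 23.2 and 73.9 in controls. The count was 2619 without P7 Ctrl replicate 1 and 2674 without P7 Ctrl replicate 2. Of the 79 named calls, 17 were lost without P7 Ctrl replicate 1, 16 without P7 Ctrl replicate 2, 6 without P7 DKO replicate 1 and 17 without P7 DKO replicate 2, and none reversed.

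Whether the DKO change differs between the ages was tested as an interaction, the change at P7 minus that at P3. Stem cell genes were further down at P7: Plvap changed by -0.87 at P3 and -5.46 at P7 (difference -4.60 ± 0.26, adjusted p = 4.14e-05), and Pax7 turned from 1.33 to -2.52 (difference -3.85 ± 0.31, adjusted p = 0.000229). Sohlh2 and Stra8 turned the other way, from -0.54 to 2.15 and from -0.56 to 1.88. Foxc2 and Dmrt2, a gene of the Dmrt transcription factors, were further down at P7, and Cthrc1, Mdk and Lcmt2 higher (differences from 3.22 to 3.30). The lists that differed and held without each library in turn were stem cell (median difference -1.38, adjusted p = 4.22e-07, and adjusted p = 0.245 with an estimated correlation), differentiating (1.10, 1.20e-05 and 0.099 in the same order), meiotic (0.50, 0.00612 and 0.454), S phase (0.87, 2.08e-11 and 0.245) and Mage genes (1.16, 3.33e-08 and 0.156). In this test 16 stem cell genes were lower and 1 higher (1 higher and 17 lower adjusted over the list alone), 20 S phase genes higher and none lower (23 higher and 0 lower adjusted over the list alone), and 8 differentiating genes higher and none lower, also adjusted over the list alone. Of the H3K9 list Ehmt1 and Trim28 were higher and Phf8 lower, where the Trim28 call was lost under quantile normalization and that of Phf8 with median-centring. Of 3383 genes past the threshold 1800 were higher and 1583 lower, and 2269 and 1250 with median-centring, 1191 and 1262 after quantile normalization. The count was 2105 without P3 Ctrl replicate 2, 1752 without P3 DKO replicate 2, 1642 without P7 Ctrl replicate 1 and 1635 without P7 Ctrl replicate 2. Of 66 named calls 7 to 22 were lost without 1 library and 13 under quantile normalization.

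A further 6 lists passed in the interaction but not in every setting. Pan-germ-cell genes (adjusted p = 0.0336) and Rhox genes (0.0347) were higher, as were G2 and mitosis genes (0.00612), and piRNA (0.0347), stromal (0.0474) and endothelial genes (0.0326) lower. With an estimated correlation these gave adjusted p = 0.612, 0.245, 0.72, 0.612, 0.669 and 0.612. Under quantile normalization the pan-germ-cell list turned down (0.819), and G2 and mitosis (0.121), stromal (0.309) and endothelial genes (0.0888) did not pass. Without a filter on low values the Rhox (0.11), piRNA (0.0557) and stromal calls (0.0514) ended. Leaving out P3 Ctrl replicate 1 ended the piRNA (0.0539) and Rhox calls (0.0645), and leaving out P3 Ctrl replicate 2 the G2 and mitosis (0.162) and stromal calls (0.153). Without P3 DKO replicate 1 the piRNA (0.0753), Rhox (0.0635) and stromal calls (0.0765) ended, and without P7 Ctrl replicate 1 the stromal call (0.0506). Without P7 DKO replicate 1 piRNA (0.0546), G2 and mitosis (0.0546), stromal (0.0995) and endothelial genes (0.0504) did not pass, and without P7 DKO replicate 2 pan-germ-cell (0.0635), Rhox (0.0609) and stromal genes (0.0609).

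The change with age in controls compares P7 Ctrl with P3 Ctrl, both Cre-carrying double heterozygotes, so it is not that of wild type. From P3 WT to P7 Ctrl 722 genes passed as higher and 686 as lower in limma. The 4 lists that passed with age had medians of opposite sign in P3 Ctrl against P3 WT. These were 0.286 for pluripotency, 0.301 for imprinted, -0.65 for G2 and mitosis and -0.211 for H3K9 genes. The shared P3 Ctrl libraries alone push towards opposite signs. Estimated depth was 38.5 to 42.7 M in P3 Ctrl and 21.3 to 24.5 M in P7 Ctrl. Dnmt3l, the cofactor of de novo DNA methylation (chromosome 10, 78041947 to 78063622), fell from 15.9 ± 2.87 to 0.491 ± 0.112 RPKM (log2 change -3.50 ± 0.51, adjusted p = 0.00329) and Piwil4 from 24.3 ± 0.456 to 11.8 ± 1.03 RPKM. The list of de novo methylation and piRNA pathway genes that holds both had 3 higher and 5 lower of 22 (3 higher and 8 lower adjusted over the list alone) and did not pass (adjusted p = 0.236). Plvap rose from 15.8 ± 1.16 to 79.4 ± 0.225 RPKM and the stem cell RNA-binding protein gene Nanos2 from 2.81 ± 1.59 to 11.4 ± 1.04 RPKM. Without a filter on low values the calls of Piwil4 and Nanos2 were lost, and that of Piwil4 also with a pseudocount of 0.1. Rspo2, a secreted activator of Wnt signalling (chromosome 15, 43020794 to 43170826), rose from 2.43 ± 0.998 to 28 ± 1.05 RPKM (log2 change 3.11 ± 0.38, adjusted p = 0.00211). The keratins Krt18, Krt7 and Krt8 fell, Krt18 from 36.4 ± 19.3 to 0.885 ± 0.16 RPKM.

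The pluripotency list had 10 of 19 lower with age and 1 higher (1 higher and 11 lower adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.311 with an estimated correlation), with Sox2, Esrrb, Alpl and Dppa2 among those that fell. The imprinted list had 12 of 32 lower and none higher (0 higher and 14 lower adjusted over the list alone, adjusted p = 0.0147, and adjusted p = 0.311 with an estimated correlation), with Grb10, a growth-restricting adaptor gene, falling from 30.1 ± 10.6 to 2.97 ± 0.00475 RPKM. G2 and mitosis genes had 4 of 27 higher (3 higher and 0 lower adjusted over the list alone, adjusted p = 0.0049, and adjusted p = 0.84 with an estimated correlation), among them Hmmr and Ndc80. H3K9 genes had 4 higher and 3 lower of 25, also adjusted over the list alone (adjusted p = 0.0469, and adjusted p = 0.311 with an estimated correlation): the methyltransferase Suv39h1 rose from 38.1 ± 4.36 to 76 ± 1.01 RPKM, Setdb2, Atf7ip and Phf8 rose, and Hr, Phf2 and Kdm1a fell. The G2 and H3K9 calls were lost without P3 Ctrl replicate 1 (adjusted p = 0.204 and 0.118), and the H3K9 call without P7 Ctrl replicate 2 (0.0612) and under quantile normalization (0.169). Stem cell genes had 9 higher and 3 lower of 32 (9 higher and 4 lower adjusted over the list alone, 0.141), and differentiating genes 2 higher and 7 lower of 15 (3 higher and 8 lower adjusted over the list alone, 0.137), with Kit falling from 27.3 ± 0.932 to 7.68 ± 0.593 RPKM. Endothelial markers had 1 higher and 6 lower of 8, also adjusted over the list alone (0.0654), Pecam1 among the latter. Hypoxia targets had 8 of 22 lower (1 higher and 8 lower adjusted over the list alone, 0.0654), among them Adm and Ldha, and p53 targets 7 of 23 lower (2 higher and 7 lower adjusted over the list alone, 0.354), among them Cdkn1a and Perp. Sertoli markers had a median of 0.64 and did not pass (0.343), but did without the pair of libraries with high Sertoli transcripts (0.000722). Of 3441 genes 1468 were higher and 1973 lower at P7, and 1587 and 1424 after quantile normalization. Other large rises were Hmgn5, Gjb2, Ppfibp2, Basp1, Barhl2 and Brwd3 (log2 changes from 2.20 to 2.58) and other large falls Gsc, Sdc3, Plac8 and Dapk1 (from -3.50 to -3.21). The count was 673 without P3 Ctrl replicate 1, 556 without P7 Ctrl replicate 1 and 486 without P7 Ctrl replicate 2. Of 78 named calls 47, 47 and 51 were then lost, and 20 without P3 Ctrl replicate 2. Without a filter on low values 21 were lost, among them those of Hmgn5, Basp1 and Perp, and under quantile normalization 12, that of Perp included.

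Against P3 Jmjd1bKO, the question being what loss of Jmjd1a adds, the same P3 DKO libraries enter as against P3 Ctrl, so this is no separate test of their changes. Rrm2 was lower at 21 ± 1.39 against 49.2 ± 10.1 RPKM, Stra8 at 21 ± 0.409 against 54.6 ± 21.8 and Uhrf1 at 116 ± 9.7 against 200.3 ± 9.01 RPKM (adjusted p = 0.018, 0.0197 and 0.0199). Dnmt3l was higher at 35.7 ± 1.98 against 10.7 ± 8.35 RPKM (adjusted p = 0.0363). S phase genes had 21 of 28 lower (0 higher and 25 lower adjusted over the list alone, adjusted p = 3.26e-15, and adjusted p = 0.362 with an estimated correlation), G2 and mitosis genes 14 of 27 lower (0 higher and 26 lower adjusted over the list alone, adjusted p = 2.85e-11, and adjusted p = 0.576 with an estimated correlation) and Rhox genes 7 of 13 higher (9 higher and 0 lower adjusted over the list alone, adjusted p = 8.80e-05, and adjusted p = 0.0702 with an estimated correlation). These list calls held without each of the 4 libraries in turn. Stromal markers did not pass (0.876). Their median was 0.567 without the pair of libraries with high Sertoli transcripts, which leaves 1 P3 Jmjd1bKO library. Of the H3K9 list Ehmt2 and Phf8 were higher and Suv39h1, Ehmt1, Cdyl and Uhrf1 lower. Cd209c, Dbhos, Nol4 and C3 were higher by 2.34 to 4.43, and Ifi27l2a, Lgals1 and Krt17 lower, with log2 changes from -2.02 to -1.74. Of 2435 genes 1275 were higher and 1160 lower, a balance that turned with scaling, at 1089 and 1298 with median-centring and 903 and 645 after quantile normalization. Without a filter on low values 2177 were higher and 1078 lower, 823 and 1006 with a pseudocount of 0.1, and 416 and 78 with an added limit of 2-fold on the filtered genes. With only the libraries of the 2 groups the count was 12. The calls of Suv39h1, Cdyl and Uhrf1 were lost under quantile normalization, that of Ehmt1 without a filter on low values, and that of Dnmt3l without a filter or with a pseudocount of 0.1. The count was 784 without P3 DKO replicate 1, 24 without P3 DKO replicate 2, 3727 without P3 Jmjd1bKO replicate 1 and 49 without P3 Jmjd1bKO replicate 2, the library with high Sertoli transcripts. Of 60 named calls 29, 57, 6 and 53 were then lost.

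Against P3 Jmjd1aKO, which asks what loss of Jmjd1b adds, 5 entries passed, beside 1674 at an unadjusted p under 0.05. Kdm3b, the gene lost in addition here, was not among them, although its mean level was lower in P3 DKO. The few calls thus do not show that its loss adds little. Exoc3l, of the exocyst family, was lower at 3.36 ± 0.224 against 9.39 ± 0.0553 RPKM (adjusted p = 0.00563). Chosen after their values were seen, Mir23a and Mir6898 were listed at 0 in P3 DKO and at 49.6 ± 6.26 and 43.3 ± 4.1 RPKM in P3 Jmjd1aKO, and Mir345 at 0 in P3 Jmjd1aKO and 19.1 ± 10.1 RPKM in P3 DKO. The count was 11 without P3 DKO replicate 2 and 13 without P3 Jmjd1aKO replicate 1. S phase genes were lower as a list, at a median of -0.30 with 4 of 28 lower adjusted over the list alone and none over all genes (adjusted p = 1.33e-10, and adjusted p = 0.571 with an estimated correlation). Without the pair of libraries with high Sertoli transcripts, which leaves 1 P3 Jmjd1aKO library, the S phase median was -0.18 and the stromal median 0.189. With all libraries the stromal list did not pass (adjusted p = 0.376). Rhox genes were higher at a median of 0.25, and 0.16 without the pair (adjusted p = 0.00857, and adjusted p = 0.377 with an estimated correlation), but not without P3 Jmjd1aKO replicate 1 (0.0546). The piRNA list was higher, and the Sertoli, Leydig, leukocyte and G2 and mitosis lists lower (adjusted p = 0.0163, 0.00128, 0.00449, 0.0257 and 2.77e-05). With an estimated correlation these gave adjusted p = 0.571, 0.577, 0.571, 0.571 and 0.577, and without P3 Jmjd1aKO replicate 2, the library with high Sertoli transcripts, 0.284, 0.783, 0.672, 0.284 and 0.651. The piRNA call also ended without P3 DKO replicate 1 (0.108) and the leukocyte call without P3 DKO replicate 2 (0.103).

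Whether the loss of both genes differs from the sum of the single losses was tested as an interaction on the log2 scale. It gave 5 entries. Of these Mir345, Mir6898, Mir8105 and Mir93, chosen after their values were seen, came from zeros in 1 or more groups. At an unadjusted p under 0.05 there were 2157. S phase genes were lower than the sum at a median of -0.36 over 28 genes, with 2 lower adjusted over the list alone (adjusted p = 4.28e-07, and adjusted p = 0.442 with an estimated correlation). Pcna stood at 269 ± 26.8, 214 ± 21.1, 280.3 ± 14.3 and 174 ± 9.74 RPKM in P3 Ctrl, Jmjd1aKO, Jmjd1bKO and DKO. G2 and mitosis, Sertoli, Leydig, stromal and immediate early lists were also lower than the sum (adjusted p = 8.30e-06, 6.62e-06, 0.000379, 0.0282 and 0.0273), and piRNA and Rhox genes higher (0.00524 and 0.0339). With an estimated correlation these 7 gave adjusted p from 0.442 to 0.471. Without both libraries with high Sertoli transcripts, which leaves 1 library of each single knockout, these 7 did not pass. The S phase median was then smaller at -0.18. Leaving out 1 library at a time ended the Rhox call without P3 Ctrl replicate 1 (0.0839), P3 DKO replicate 1 (0.0522), P3 Jmjd1aKO replicate 1 (0.0931) and either P3 Jmjd1bKO library (0.0667 and 0.0557). The piRNA call ended without P3 Jmjd1bKO replicate 2 (0.0557), and the immediate early call without P3 Ctrl replicate 2 (0.171) or P3 DKO replicate 1 (0.065). The stromal call ended without P3 Ctrl replicate 2 (0.193) or replicate 2 of P3 Jmjd1aKO (0.177) or P3 Jmjd1bKO (0.312). The gene count was 10 without P3 Jmjd1aKO replicate 1 and 8 without replicate 1 of P3 Ctrl, P3 DKO or P3 Jmjd1bKO.

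P3 Ctrl against P3 WT compares Cre-carrying double heterozygotes with wild type. Estimated depth was 38.5 to 42.7 M fragments in P3 Ctrl and 13.2 to 14.6 M in P3 WT. Genotype and Cre cannot be told apart from this difference or from the higher Amh of P3 WT. Mitotic genes were lower in P3 Ctrl as a list: none of 27 passed alone, 19 were lower adjusted over the list alone and the median was -0.65 (adjusted p = 9.98e-12, and adjusted p = 0.585 with an estimated correlation). Top2a, the mitotic topoisomerase, stood at 114 ± 24.5 against 191 ± 7.63 RPKM (log2 -0.75 ± 0.21, adjusted p = 0.0835). Cbx3, the heterochromatin protein HP1 gamma, fell from 362 ± 22.9 to 231 ± 11.2 RPKM (log2 change -0.65 ± 0.10, adjusted p = 0.0352), and Rhox1 rose from 13.4 ± 1.19 to 24.1 ± 0.802 RPKM (adjusted p = 0.035). S phase and H3K9 lists were also lower (adjusted p = 1.33e-05 and 0.00309) and Rhox, imprinted and endothelial lists higher (0.00624, 0.00883 and 0.00624). With an estimated correlation these 5 gave adjusted p = 0.585, 0.202, 0.202, 0.225 and 0.585. All 6 list calls held without each library in turn, and the imprinted call ended without a filter on low values (adjusted p = 0.0705). Beside these stand the lower depth and higher Amh of P3 WT: the Sertoli list, at a median of -0.89, did not pass with all libraries (0.292) and was lower in P3 Ctrl without the pair of libraries with high Sertoli transcripts (1.88e-05). Stard10, Ankrd55, Luzp4 and Krt27 rose by 1.67 to 1.92 on the log2 scale, Gucy2c fell by 1.96, and AI662270 and Cbln2 fell. Of 104 genes 60 were higher and 44 lower, and 50 and 55 with median-centring. The count was 4 without P3 Ctrl replicate 1, 231 without P3 Ctrl replicate 2 and 7 without either P3 WT library. Of 11 named calls, all were lost without P3 Ctrl replicate 1 or either P3 WT library and 2 without P3 Ctrl replicate 2. Quantile normalization ended 6, those of Kdm3a, Kdm3b, Stard10, Ankrd55, Gucy2c and Cbx3. Without a filter on low values 4 ended, those of Kdm3b, Stard10, Ankrd55 and Gucy2c, and with a pseudocount of 0.1 those of Gucy2c and Cbln2.

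Finally, changes were compared across genes between comparisons, where genes are not independent replicates. The DKO changes at P3 and P7, which share no library, correlated at r = 0.105, within the range of -0.128 to 0.211 given by 100 simulated draws with no change. Each gene was drawn with its own spread, so the most variable genes weigh most in r. A value within this range thus does not exclude a shared change. Of genes past the threshold at both ages 86 were higher in both against 56 expected by chance, 117 lower in both against 54.7, and 113 opposite against 111. The P7 DKO change ran against the change from P3 WT to P7 Ctrl at r = -0.313 and a covariance of -0.122, while the shared P7 controls alone gave -0.505 and -0.0678 in simulation, so the correlation lay closer to 0 and the covariance further from it. Of the calls, 580 genes past both thresholds were opposite against 236 expected. The shared controls also push genes towards opposite calls, which the expected number leaves out. For the single losses the simulated values are not matched to the data, as their spread was estimated without the single knockout groups. The SD between replicates was highest in these groups, at 0.459 in P3 Jmjd1aKO and 0.508 in P3 Jmjd1bKO (0.292 to 0.404 in the others). Departures from the simulated values below are thus not read as effects. Loss of Jmjd1a and joint loss at P3 correlated at r = 0.542, where the shared P3 controls alone gave 0.503, with a covariance of 0.12 against 0.0686. For loss of Jmjd1b and joint loss r was 0.169, below the simulated range of 0.398 to 0.605. The single losses correlated at r = 0.527 against 0.505 simulated (covariance 0.0937 against 0.069). Without the libraries with high Sertoli transcripts r was 0.305, from 1 library of each single knockout, a design that was not simulated. P3 DKO against P3 Ctrl and P3 Ctrl against P3 WT correlated at r = 0.0509, where shared controls alone gave -0.497.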

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

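Each value listed here is a difference between the DKO changes at P7 and P3 in a named gene or list, tested as an interaction that was set before the data were examined, while the tests that weigh explanations for the 3 patterns were chosen after the results were seen. Of 111 genes named for the DKO comparisons 68 passed it. The 111 genes were named for changes at either age, so this share is not that of all genes, of which 3383 of 14772 passed. Of the 68, 32 have changes of opposite sign at the 2 ages. That number counts signs alone, and some changes lie near 0, as for Nxf2 at P3 (-0.00175) and Dppa3 at P7 (-0.0693). Under quantile normalization the interaction calls of Dppa3, Ccna2, Cdca8, Trim28, Slc2a1 and Pdgfra were lost, without a filter on low values those of Dppa3, Nanog, Cdca8 and Snrpn, and with a pseudocount of 0.1 those of Dppa3 and Eda2r. Genes not named for the interaction itself were not run under these settings. The values are log2 changes at P7 minus those at P3, with adjusted p under the threshold of limma for each.

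Among stem cell genes the differences were Plvap (-4.60), Foxc2 (-3.76), Pax7 (-3.85), T (-3.26), Lhx1 (-2.67) and Sox3 (1.02). Among genes of differentiation and meiosis they were Dmrtb1 (3.14), Rhox13 (1.76), Sohlh2 (2.69), Stra8 (2.44), Gm1564 (1.78) and Sycp1 (1.44). Pan-germ-cell and piRNA pathway genes gave Taf7l (1.38), Nxf2 (0.94), Piwil4 (-2.31), Exd1 (-1.24), Tdrd7 (-1.26) and Tdrd1 (-0.64). Pluripotency and spermatid genes gave Pou5f1 (-1.40), Nanog (1.41), Dppa3 (-1.5), Spaca1 (1.38), Tnp1 (-2.18), Odf2 (0.74) and Ldhc (-1.58). Cell cycle genes gave Ccna2 (1.08), Rrm2 (1.77), Mcm5 (1.26), Cdc6 (1.43), Rrm1 (0.90), Cdca8 (0.50), Ccne2 (1.40), Gins2 (1.68) and Ccne1 (1.36). The Magea genes gave Magea4 (2.76), Magea2 (2.55), Magea3 (2.54) and Magea6 (2.32), and imprinted genes H19 (-3.39), Peg10 (-0.84), Mirg (-1.30), Igf2 (-1.99), Rian (-3.03) and Snrpn (1.93). Kdm3a itself differed by -0.61, and the H3K9 cofactor Trim28 by 0.61. p53 and hypoxia targets gave Plk2 (1.01), Eda2r (1.19), Xpc (-1.02) and Slc2a1 (0.72), and stromal and endothelial markers Pdgfrb (-2.54), Pdgfra (-1.77), Kdr (-2.18) and Cdh5 (-1.51). The remaining genes gave Cd209c (2.72), Dbhos (2.44), Otx2 (-2.02), Ndrg2 (-2.47), Gabbr1 (-1.33), Nxph4 (-1.57), Gpsm3 (-1.90), Cthrc1 (3.22), Ly6k (2.47), H2-K1 (2.18), Prrx2 (-2.69), Smkr-ps (-3.20), Dlx3 (-2.66) and Sphk1 (-2.33).

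Of the lists, the median differences were -1.38 for stem cell, 1.10 for differentiating, 0.50 for meiotic, 0.87 for S phase, 1.16 for Mage, 0.56 for pan-germ-cell, 0.41 for G2 and mitosis, 0.46 for Rhox, -0.18 for piRNA pathway, -0.58 for stromal and -0.86 for endothelial genes. None of the 11 passed with an estimated correlation, where adjusted p ran from 0.099 to 0.72.

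Replicate 2 of P3 Jmjd1aKO and of P3 Jmjd1bKO held more Sertoli, stromal and Leydig transcripts than replicate 1, by a median of at least 0.809 on the log2 scale in each list and genotype, which suggests more somatic testis cells or their RNA in these preparations. Clu, Inha and Amh stood at 255, 165 and 108 RPKM in the former and 312, 206 and 149.6 RPKM in the latter. Against an effect of the genotype, the Sertoli list in replicate 1 lay at most 0.115 above P3 Ctrl. Against low depth, it lay at least 2.29 above the shallower P3 WT. Not every somatic list rose: endothelial markers differed by -0.436 and -0.507, leukocyte markers by -0.0999 and -0.0267, while erythroid markers rose by 1.67 and 1.04. How the cells were isolated for these libraries stays open, as the labels state no sort.

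At P7 stem cell genes were lower and differentiation genes higher in DKO, list calls that are lost with an estimated correlation (adjusted p = 0.134 and 0.12). Scaling does not account for it, as the stem cell median was -1.58 or lower under median-centring and quantile normalization. Somatic cells replacing germ cells would lower the pan-germ-cell list, whose median change was 0.196 (0.0621 after quantile normalization). That list cannot decide it, as it holds the meiotic genes Sycp3 and Hormad1, which rose with the pattern in question. Ddx4 stood at 239.8 and 237.6 RPKM in P7 Ctrl and 198.8 and 169.5 in P7 DKO. Dazl stood at 381.9 and 396 RPKM in P7 Ctrl and 582.3 and 613.1 in P7 DKO. Sertoli, Leydig, stromal and leukocyte lists, which such a replacement would raise, did not pass (medians -0.0442, -0.00129, 0 and 0.0134). Loss of endothelial cells would need an endothelial fall as deep as that of the stem cell list, but its median was -0.534 on a log2(RPKM + 1) scale that shrinks changes at low levels. Kdr fell from 3.71 to 0.316 RPKM and Cdh5 from 2.77 to 0.217, while Egfl7, the most abundant of the list, stood at 19.4 and 25 RPKM in P7 Ctrl and 15.1 and 14.2 in P7 DKO. Fewer endothelial cells may thus accompany the change. With age in controls Plvap rose, while Pecam1 fell from 17.4 and 7.95 RPKM in P3 Ctrl to 1.53 and 1.61 in P7 Ctrl. Egfl7 and Cdh5 also fell with age, and Kdr rose from 1.68 and 1.98 to 3.66 and 3.76 RPKM. Most of the endothelial list thus did not follow Plvap with age, and only an endothelial share of its RNA stays open. A smaller share of stem cells and a lower level per cell, both of which could follow from loss of the demethylases as a hypothesis, are not told apart in bulk RNA.

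At P3 S phase genes were lower in DKO. Scaling left the list median at -0.452 or lower, and each of the 4 pairings of a DKO with a control library gave -0.406 or lower. Fewer germ cells would lower pan-germ-cell genes alike, whose median change was -0.115. Stromal markers ran higher in P3 DKO (median 0.54, adjusted p = 0.117, and 0.00102 without the pair of libraries with high Sertoli transcripts), so a larger share of stromal RNA in these preparations stays open. The S phase list does not pass with an estimated correlation, and whether fewer germ cells were cycling was not tested. P3 litters and the days of collection are not in the labels and stay untested.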

How the results depend on the processing

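The settings without small RNA entries, without the pair of libraries with high Sertoli transcripts, and without single libraries for the lists were chosen after seeing the data. Where a value moved, the cause was not tested, except that an added 2-fold limit lowers what can pass by construction. With 2 libraries per group and a depth known only as an estimate, small changes and genes near 0 RPKM are not resolved.

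No named gene reversed under any setting run. Of 354 calls of named genes 344 held with median-centring, 295 with quantile normalization, 323 with a pseudocount of 0.1, 300 without a filter and 351 with replicate number as a covariate. Of 1696 tests of them without 1 library 1024 held and 672 lost the call. Of 67 list calls all held with median-centring, 56 with quantile normalization, 62 with a pseudocount of 0.1, 60 without a filter and 66 with replicate number as a covariate. They held in 28 cases in fry, 35 in its mixed form, 1 with an estimated correlation and 39 without the pair of libraries with high Sertoli transcripts. In 344 list tests without 1 library 274 held, 64 lost the call and 6 reversed.

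Counts of changed genes moved by over 1.5 times as follows. In Ctrl against WT, 104 became 47 with quantile normalization, 183 with a pseudocount of 0.1, 776 with replicate number, 1665 with array weights, 43 with the 2-fold limit, 20 with only the groups compared and 2199 without the high-Sertoli pair. In P3 Jmjd1aKO, 5 became 9 with quantile normalization, 3 with the pseudocount, replicate number or array weights, 12 without a filter, 9 with only the groups compared, 3 without small RNAs and 10 without that pair. In P3 Jmjd1bKO, 3 became 7 without a filter, 9 with only the groups compared, 0 without small RNAs and 7 without the pair. In P3 DKO, 661 became 365 with the pseudocount, 1584 without a filter, 1140 with replicate number, 1469 with array weights, 161 with the 2-fold limit, 17 with only the groups compared and 1931 without the pair. The 2-fold limit gave 1506 in P7 DKO, 1078 with age and 1619 for DKO by age. The age count was 6006 with array weights and 5206 without the pair. P3 DKO against Jmjd1aKO gave 170 without a filter, 18 with only the groups compared and 2 without small RNAs. Against Jmjd1bKO it gave 1548 with quantile normalization, 1017 with array weights, 494 with the 2-fold limit, 12 with only the groups compared and 795 without the pair. The departure from the sum of single losses gave 72 without a filter, 1 without small RNAs and 10 without the pair.

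Without 1 library the counts ran from 4 to 231 in Ctrl against WT, 5 to 6 in P3 Jmjd1aKO, 3 to 7 in P3 Jmjd1bKO, 10 to 150 in P3 DKO, 2619 to 4427 in P7 DKO, 486 to 2506 with age, 4 to 13 and 24 to 3727 for P3 DKO against Jmjd1aKO and Jmjd1bKO, 1635 to 3316 for DKO by age and 5 to 10 for the departure from the sum. The adjusted p of lists that reversed without a library ran in P3 Jmjd1bKO from 0.00158 to 0.916 for piRNA, 4.60e-13 to 0.769 for G2 and mitosis, 9.76e-11 to 0.916 for Sertoli and 0.00757 to 0.916 for endothelial genes, and from 1.02e-07 to 0.783 for Sertoli genes in P3 DKO against Jmjd1aKO.

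Without the high-Sertoli pair, lists that reversed were Leydig in P3 Jmjd1aKO (adjusted p = 0.957), piRNA, Sertoli and endothelial (each 0.86) and G2 and mitosis (0.641) in P3 Jmjd1bKO, Sertoli (0.437) and Leydig (0.969) in P3 DKO against Jmjd1aKO, and G2 and mitosis (0.985), Sertoli (0.449) and stromal (0.252) in the departure from the sum. With quantile normalization the pan-germ-cell list reversed in DKO by age (0.819), and the correlation of the Ctrl against WT and P3 DKO changes moved to -0.0055. Without the high-Sertoli pair, which leaves 1 library of each single knockout, that of the single losses moved to 0.305.

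The replicate numbers were checked as a pairing by the correlation of replicate differences between groups. It passed 0.1 in 7 of 21 pairs of groups, among them P3 Ctrl with Jmjd1aKO (0.169), Jmjd1bKO (0.194) and DKO (0.134), and the single knockouts with each other (0.581), whose second libraries share the Sertoli transcripts. As it did not in every pair (-0.13 at the lowest), samples were not paired. With replicate number as a covariate the counts of Ctrl against WT, P3 Jmjd1aKO and P3 DKO moved by over 1.5 times, and no other did.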

Other observations

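The tests in this part were written down before their results were seen, although the first arose from the Rhox and Mage results. X-linked genes rose more often than others in P7 DKO: with the Rhox and Mage lists left out, 31.1% of 540 X-linked genes passed as higher, against 16.7% of the others (odds ratio 2.25, 95% interval 1.85 to 2.72, Fisher's exact test, two-sided, adjusted p = 6.73e-15 over 12 tests). They fell less often (odds ratio 0.425, adjusted p = 1.32e-08). At P3 the odds ratio for higher genes was 1.41 (adjusted p = 0.174) and for lower genes 0.232 (adjusted p = 0.00436). The difference between the ages, tested as the DKO by age interaction, did not pass for higher genes (odds ratio 1.21, 95% interval 0.937 to 1.56, adjusted p = 0.134) and passed for lower genes (odds ratio 0.563, adjusted p = 0.00132), so an excess of X-linked rises at P7 over P3 is not shown. Genes are not independent replicates in these counts.

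Chromosome carried over from a donor strain around the targeted genes would place changed genes near them. Within 10 Mb of Kdm3a or Kdm3b 3 of 156 genes passed in P3 DKO, namely Gfra3, Polr2d and Prelid2 on chromosome 18, with the targeted genes left out. The odds ratio was 0.417 (95% interval from 0.0848 to above 1, Fisher's exact test, two-sided, p = 0.168). No excess of changed genes near the targeted genes was thus seen. As the interval reaches above 1, a modest excess is not excluded.

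If P3 DKO germ cells resembled younger cells, their changes would run against the change with age. The age change used here, from P3 WT to P7 Ctrl, also spans a difference in genotype, Cre and estimated depth. The test cannot separate these from age. Across genes the P3 DKO change and the change from P3 WT to P7 Ctrl, which share no library, correlated at r = 0.0517. The simulated range without change was -0.166 to 0.163, in which the most variable genes weigh most. Of genes past both thresholds 36 were higher in both against 15.7 expected by chance, 46 lower in both against 15.7, and 21 opposite against 31.5. The predicted negative correlation was thus not seen. Whether P3 DKO germ cells resemble younger cells is not decided by this, as genotype, Cre and depth differ along the same change.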
